A study of Mus musculus with 5 samples.

How the data were processed

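Bulk RNA was sequenced from cultured peritoneal macrophages of mice, in 3 wild-type libraries and 2 libraries from mice in which Cre recombinase under the lysozyme M promoter removes floxed Nrp1 in myeloid cells. Per the labels' protocols, poly(A) RNA was selected from 1 µg of total RNA, libraries were made with an Ion Torrent whole-transcriptome kit, and the reads were processed with Torrent Suite 4.4 and its Whole Transcriptome Analysis Plugin 4.2-r7. The submitters' processing notes name TopHat2, Bowtie2 and Cufflinks, without versions, and the mm10 build. The deposited values are FPKM per gene, per the file headers, that is, fragments scaled by transcript length and by the number of mapped reads, as Cufflinks estimates them. The table has 38757 rows. A further 17 deposited columns, which hold ratios, logarithms and averages derived from the FPKM, were not used. The labels say that wild-type replicate 3 is the library with raw data; no batch or date is given. Nothing in the labels says whether libraries of a group came from separate animals, so p-values measure only the spread between these samples.

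The table's gene names were sorted with hyphens ignored, with 0 neighbouring rows out of order under that rule. The values of wild-type replicate 3 followed another sort, in which the hyphen counts as a character, so that 2144 rows in 73 runs held another gene's value for that library. In the 722 displaced rows with a mean log2(FPKM + 1) of at least 1 in the other 4 libraries, Pearson's r across genes between wild-type replicate 3 and that mean was 0.171 as deposited and 0.916 after the values were put back in the hyphen-counting order. In the 11381 other expressed rows it was 0.944. The same reordering applied to wild-type replicate 1 lowered its r in such rows from 0.981 to 0.127. Of the 19 runs with at least 5 expressed rows, all 19 had a higher r after reordering and 18 reached at least 0.8. The comparison therefore used the realigned column. Of the genes named in the text 12 stood in displaced rows, namely Ear2, Fpr1, Fth1, H2-Eb1, Naip1, Ndufa6, Nnt, Npc1, Tpi1, mt-Nd3, mt-Nd6 and mt-Ti, and for 5 of them (Ear2, H2-Eb1, Nnt, Tpi1 and mt-Nd3) the fold change had the other sign in the order as deposited. This choice was made after the data were examined, and both the order as deposited and the removal of genes with displaced rows were added as alternatives at that point. An estimated correlation together with quantile normalization, or without wild-type replicate 1 or 3, was added later. The reordering was tested on a misordered copy of wild-type replicate 1, which it restored.

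Rows with a number in place of a gene name (27 rows, as a spreadsheet makes of names that look like dates) and rows whose names differ only in case (50 rows) were left out. FPKM were summed over rows for the 165 symbols with several rows, leaving 38463 symbols. A gene was tested when its FPKM was at least 1 in at least 2 libraries, which 12214 genes met. Knockout was compared with wild-type by limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with genotype as the single term, a moderated test with a mean-variance trend and Benjamini-Hochberg adjustment, at a threshold of 0.05. All 5 libraries entered the fit. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Alas2 was listed at 7.3e-95 FPKM in one library, far below the worth of a single read, so values were not whole multiples of a read and the sequencing depth is unknown. The gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, over the 33 lists with at least 5 tested members, with an estimated correlation and fry as alternatives. The estimated correlation rests on these 5 libraries alone, and the simulation below did not run it, so its power is unknown. List medians are given relative to the median of all tested genes, which was 0.11 on the log2 scale in the fit as reported, 0.19 when libraries were rescaled to equal sums and -0.0043 under median-of-ratios scaling.

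Named genes followed a rule fixed before the data were examined. It takes Nrp1 and Lyz2, and in each direction up to 12 genes past the threshold with the largest fold change, a mean FPKM of at least 5 and no overlap between the groups. Where fewer than 5 qualify, a direction is filled to 8 with the genes of smallest unadjusted p that meet the level and overlap conditions. Predicted gene models and small RNAs named as microRNAs, small nucleolar RNAs, Cajal body RNAs or n-R RNAs are left out of this choice, which does not cover mitochondrial tRNAs such as mt-Ti. From each list, 2 to 4 members with the smallest unadjusted p were added, of which some are not reported here. Data were simulated with these genes' means and spreads, in 5 draws with 200 changed genes each, picked from genes of about 5 FPKM or more. The test recovered 13.2% of genes changed 2-fold, 64.0% of those changed 4-fold and 88.4% of those changed 8-fold. A list shifted by 0.5 was called in 5 of 5 draws at the preset correlation. Noise was independent between genes and equal in spread between libraries. The simulation thus held neither correlated genes nor a deviating library, and its rates may not carry over to these data. Of 698 calls in those data 47 were of unchanged genes. Without wild-type replicate 3, 29.6% of genes changed 2-fold were recovered. The other alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, 3 other scalings, 2 other variance models, library weights, another treatment of repeated symbols, the replicate number as a block, an adjusted p threshold of 0.1 and leaving out each library. Wild-type replicate 3 has no partner of its number, so the block takes it out of the comparison and largely repeats its removal. Library weights gave that library 0.128, the lowest of all, and so come near to its removal too. A change of sign was counted as a reversal only where the gene or list was past the threshold in at least one of the settings compared, a rule set after the values were seen. The alternatives that need raw counts were not run, since the values are FPKM. Coordinates are from GENCODE M21 and, for Nnt, from the RefSeq annotation, both on GRCm38, which is the mm10 assembly. Figures were drawn with matplotlib 3.10.9.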

Results

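Messenger RNA was measured in peritoneal macrophages, the phagocytes that reside in the mouse abdominal cavity, from wild-type mice (3 libraries) and from mice carrying floxed Nrp1 with Cre recombinase in myeloid cells, here called knockout (2 libraries). Nrp1 encodes neuropilin 1, a co-receptor for semaphorins and vascular endothelial growth factors. The FPKM of a library summed to between 539100 and 629100, and between 11014 and 12020 genes had at least 1 FPKM. The highest sum and the lowest gene number both belonged to wild-type replicate 3. Among the other 4 libraries Pearson's r across tested genes was 0.966 to 0.972, and wild-type replicates 1 and 2 (0.966) were no closer to each other than to the knockout libraries (0.969 to 0.972). Wild-type replicate 3 had r of 0.929 to 0.938 with the rest. Macrophage genes were expressed in both groups. Emr1, which encodes the F4/80 antigen, stood at 183 to 222 FPKM, Csf1r at 765 to 1108 and Gata6, the transcription factor of the large peritoneal macrophage, at 7.01 to 9.82. Other markers of that cell varied widely. Prg4 stood at 53.9 to 147 FPKM, Timd4 at 2.60 to 10.8, Selp at 0.757 to 2.52 and Aspa at 0.298 to 0.749.

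**Figure D1:**
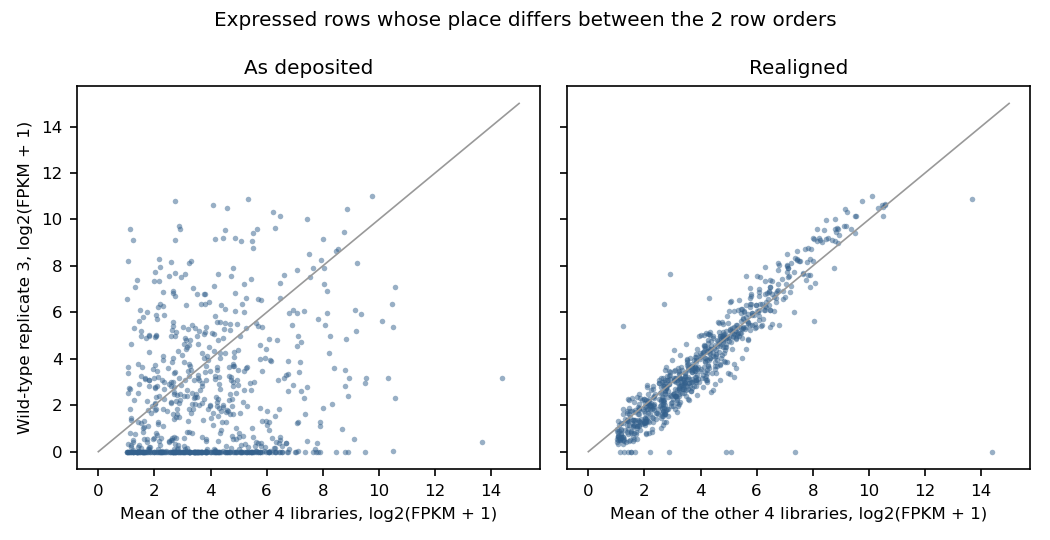
Each point is an expressed gene whose row is displaced in wild-type replicate 3, with the mean log2(FPKM + 1) of the other 4 libraries against that of wild-type replicate 3 as deposited and after the values were put back in the hyphen-counting order. Pearson's r across these 722 genes is 0.171 as deposited and 0.916 after reordering.

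Nrp1 transcripts were lower in both knockout libraries than in every wild-type library. The gene lies on chromosome 8 at 128358604 to 128503363 of GRCm38. Wild-type replicates 1, 2 and 3 had 24.3, 19.0 and 11.5 FPKM, and knockout replicates 1 and 2 had 7.63 and 7.70. The log2 fold change was -1.09 ± 0.32 (SE), with a limma adjusted p of 0.93. With 3 against 2 libraries the smallest two-sided exact permutation p is 0.2, which is what Nrp1 gave, so a permutation test of 1 gene cannot reach 0.05 in this design. Without wild-type replicate 3 the difference was -1.37, with an adjusted p of 0.16, and with library weights it was -1.43 and passed, with a limma adjusted p of 0.023. The weights were 0.128 for wild-type replicate 3, which had the lowest wild-type value, and 2.56 for wild-type replicate 1, which had the highest. The tested genes of the mesothelial and fibroblast list also had lower means in the knockout. Bgn stood at 9.08, 7.47 and 3.76 FPKM in the wild-type and 3.71 and 2.83 in the knockout libraries, and Sparc at 19.1, 17.0 and 8.59 against 9.20 and 8.62. The labels do not say which exons were removed, so reads from the remaining part of the gene can count toward these values.

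Lyz2, the macrophage lysozyme gene that carries the Cre driver, was the one named gene past the threshold. It lies on chromosome 10 at 117277331 to 117282321 of GRCm38. It was listed at 0 in wild-type replicates 1, 2 and 3, and at 53.0 and 64.3 FPKM in the knockout replicates (limma adjusted p = 0.00042). Its neighbour and paralog Lyz1, at 117287797 to 117292868, had 2361, 2071 and 832 FPKM in the wild-type libraries and 4680 and 5154 in the knockout libraries, a log2 fold change of 1.62 ± 0.50 (SE) that did not pass (limma adjusted p = 0.93). The value of 1.62 became 1.15 without wild-type replicate 3. The longest coding transcripts of both genes share 15.4% of the 50-base stretches of Lyz2, so reads can be split between them. A listed 0 can be a failed estimate. Fth1, the ferritin heavy chain, had 19243 to 25557 FPKM in 4 libraries, and in wild-type replicate 3 it had 0 after realignment and 8.0 in its row as deposited. The rows of Lyz2, Lyz1 and Nrp1 were not displaced.

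Across the transcriptome few genes separated the groups. Of 12214 genes tested, 5 were higher and 2 were lower in the knockout (limma adjusted p under 0.05). Besides Lyz2 the 6 others were small RNAs or unnamed transcripts, each listed at 0 in all libraries of one group and named here after their values were seen. The spread within that group was thus 0 for each call, Lyz2 included. Higher were AL590625.1, Gm13798, mmu-mir-6903 and mmu-mir-8099-2. Lower were Snord35a, a small nucleolar RNA at 24.1, 13.8 and 15.6 FPKM in wild-type and listed at 0 in both knockout libraries, and Gm14536. An unadjusted p under 0.05 was given to 145 genes on the higher side and 77 on the lower side, 1.82% of those tested. That is below the share of 0.05 expected if no gene changed, so these counts show no surplus of changed genes. The excess on the higher side depended on the scaling and on wild-type replicate 3, with 142 and 128 genes under median-of-ratios scaling, 161 and 209 with quantile normalization, 580 and 515 with library weights and 253 and 265 without that library. It stayed when libraries were rescaled to equal sums (135 and 48) and without wild-type replicate 1 (195 and 86) or 2 (337 and 170). Groups did not overlap for 20.8% of genes, where chance gives 20% for 3 against 2. Within 5 Mb of Nrp1 (20 tested) that share was 20%, and within 5 Mb of Lyz2 (31 tested, Lyz2 left out) it was 22.6%, against 20.8% elsewhere (Fisher's exact p = 1 and 0.82). Without knockout replicate 1 or 2, 0 genes were called in either direction by limma, with 36 and 41 genes higher and 34 and 26 lower at an unadjusted p under 0.05. Each of the genes listed at 0 in wild-type then has a value in a single library and falls under the filter. The number lower was 1 without wild-type replicate 1 and 7 without wild-type replicate 2.

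Among the genes named by the fixed rule, which did not pass, Prg4 stood on the higher side. Prg4, which encodes lubricin and is a marker of large peritoneal macrophages, had 68.7 ± 14.0 FPKM in wild-type (SD, n = 3) and 133 ± 19.5 in knockout (SD, n = 2), a log2 fold change of 0.96 ± 0.25 (SE). Nnt, the mitochondrial transhydrogenase that makes NADPH, had 4.4 ± 1.36 against 9.57 ± 0.793 FPKM. The co-repressor gene Cbfa2t2 had 3.97 ± 1.25 against 8.27 ± 0.621, and the glycosyltransferase gene Alg11 had 5.05 ± 0.864 against 9.32 ± 0.336. Csf2rb2, the beta subunit of the interleukin-3 receptor, had 47.7 ± 1.78 against 74.3 ± 1.36, and Sirpb1c had 11.0 ± 1.89 against 19.4 ± 2.08. The mitochondrial isoleucine tRNA mt-Ti had 36.0 ± 7.2 against 171 ± 123. On the lower side stood Cx3cr1, the fractalkine receptor, with 16.1 ± 4.65 FPKM in wild-type and 6.31 ± 1.99 in knockout, a log2 fold change of -1.21 ± 0.32 (SE). The actin-bundling gene Fscn1 had 8.89 ± 2.05 against 3.78 ± 0.306, and the collagen chaperone gene Serpinh1 had 13.1 ± 2.43 against 5.80 ± 1.30. Ier5l had 11.9 ± 1.11 against 5.54 ± 1.5, and Creld2, induced by endoplasmic reticulum stress, had 28.0 ± 3.54 against 15.7 ± 3.52. Ctla2a had 23.8 ± 10.8 against 8.91 ± 1.18 and Stap1 46.4 ± 12.9 against 24.4 ± 2.86. None of these 14 genes passed (limma adjusted p = 0.93 for each); the rule takes only genes whose groups do not overlap. The rows of Nnt and mt-Ti were displaced, and in the order as deposited the log2 fold change of Nnt was -0.14, with 40.7 FPKM in wild-type replicate 3 in place of 2.85.

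**Figure D2:**
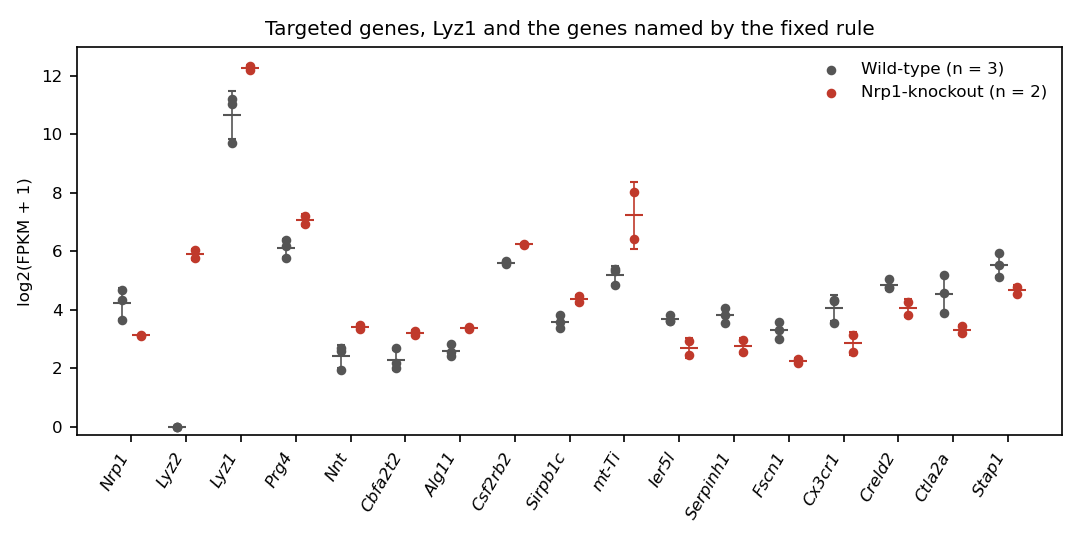
Points are log2(FPKM + 1) of each library for Nrp1, Lyz2, Lyz1 and the genes named by the fixed rule, in wild-type (grey, n = 3) and knockout (red, n = 2), with the mean as a horizontal line and the SD as a bar. Lyz2 is listed at 0 in every wild-type library, and Nrp1 is lower in both knockout libraries, at 7.63 and 7.70 FPKM.

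Genes of lipid and energy metabolism gave no called member. In fatty acid uptake and storage (26 tested, 18 with a positive fold change) and in beta-oxidation (28 tested, 19 positive), 0 members passed over all genes and 0 adjusted over the list alone, and the lists did not pass (limma camera adjusted p = 0.66 and 0.57). Acsl1, a long-chain acyl-CoA synthetase, had 30.8 ± 12 FPKM in wild-type and 49.9 ± 10.2 in knockout, and Cpt1a, the gate of fatty acid entry into mitochondria, had 47.9 ± 11.0 and 64.9 ± 1.53. Fabp3 had 14.8 ± 6.45 and 8.88 ± 1.70, and Pdk4, which holds back pyruvate oxidation, 3.39 ± 2.36 and 6.80 ± 2.44. Fatty acid synthesis (13 tested, 7 positive, adjusted p = 0.39), the TCA cycle (22 tested, 15 positive, 0.57) and the pentose phosphate pathway (8 tested, 2 positive, 0.26) did not pass either. Their first members were Mlxipl (10.4 ± 4.76 and 6.42 ± 2.04), Fasn (11.7 ± 0.821 and 10.0 ± 1.36), Suclg2 (4.91 ± 0.577 and 6.24 ± 0.237), Fh1 (17.7 ± 0.622 and 15.1 ± 2.96), Pgls (81.8 ± 36.0 and 56.6 ± 2.99) and Rpe (7.46 ± 3.18 and 9.96 ± 0.519). Several of these differences rested in part on wild-type replicate 3. Without it the log2 fold change went from 0.74 to 0.40 for Acsl1, from 0.45 to 0.30 for Cpt1a, from -0.62 to -0.31 for Fabp3 and from 0.98 to 0.44 for Pdk4. It went from -0.55 to -0.91 for Mlxipl, from -0.44 to -0.11 for Pgls and from 0.45 to 0.10 for Rpe.

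Nuclear oxidative phosphorylation genes, glycolysis and cholesterol synthesis were lower as lists with the preset correlation, and none of these calls held with an estimated correlation (adjusted p = 0.73 for each). That setting passed no list, the ribosomal one with all 76 members negative included. Fry passed 0 lists as well. The power of neither was checked, so they do not show that these lists are unchanged. The preset correlation was checked only on simulated noise independent between genes. In wild-type replicate 3 all 76 ribosomal genes stood above the mean of the other libraries, so members can move together. The calls at the preset correlation are therefore not secured either. All 3 lists had 0 members called over all genes and 0 adjusted over the list alone. For oxidative phosphorylation 40 of 48 members had a negative fold change, with a median of -0.28 relative to all genes (camera adjusted p = 1.2e-05, and 0.73 with an estimated correlation). The call ended without wild-type replicate 3 (median -0.05, adjusted p = 0.65), where these genes stood above the other libraries by a median of 0.50, in the order as deposited (-0.15, 0.37), with quantile normalization (-0.11, 0.091) and with the replicate block (-0.05, 0.68), and the median was -0.49 without wild-type replicate 2 and -0.17 with library weights. Atp5a1, an ATP synthase subunit, had 196 ± 9.97 FPKM in wild-type and 256 ± 30.8 in knockout, while Ndufa6 of complex I had 172 ± 48.9 and 120 ± 19.7. Glycolysis had a median of -0.23 (23 tested, 16 negative, adjusted p = 0.034, and 0.73 with an estimated correlation), with the glycolytic enzyme gene Tpi1 at 294 ± 108 and 191 ± 19.2 and the lactate exporter gene Slc16a3 at 68.5 ± 25.3 and 45.2 ± 4.96. That call ended without wild-type replicate 3 (median -0.07, adjusted p = 0.41) or knockout replicate 2 (-0.13, 0.50), with no filter (-0.11, 0.064), quantile normalization (-0.11, 0.38), library weights (-0.07, 0.42) and the replicate block (-0.07, 0.41). It ended at medians about as large with the removal of displaced genes (-0.20, 0.078), a filter at 5 FPKM (-0.21, 0.061), the order as deposited (-0.18, 0.10) and median-of-ratios scaling (-0.25, 0.10). Cholesterol synthesis had a median of -0.31 (21 tested, 12 negative, adjusted p = 0.014, and 0.73 with an estimated correlation), with the sterol enzymes Idi1 at 7.05 ± 0.810 and 4.08 ± 0.0505 and Cyp51 at 39.4 ± 3.24 and 26.1 ± 1.76. That call ended without wild-type replicate 3 (median -0.10, adjusted p = 0.058), wild-type replicate 2 (-0.27, 0.21) or knockout replicate 1 (-0.19, 0.19), and with quantile normalization (-0.19, 0.062), library weights (-0.07, 0.42) and the replicate block (-0.09, 0.10), and the median was -0.18 without knockout replicate 2 and -0.14 with no filter.

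Sterol efflux genes did not pass (15 tested, 8 positive and 7 negative, camera adjusted p = 0.65), with the cholesterol exporter gene Abca1 at 20.4 ± 6.10 FPKM in wild-type and 36.1 ± 8.42 in knockout and Npc1 at 35.5 ± 6.39 and 49.8 ± 4.03. On the other side stood the apolipoprotein gene Apoc1, at 41.1, 47.9 and 63.3 FPKM in wild-type and 12.4 and 44.0 in knockout (log2 fold change -1.06, and -0.18 without knockout replicate 1), and Ch25h, at 0.942 ± 0.378 and 0.359 ± 0.0204. Mitochondrially encoded transcripts (13 tested, 5 positive, adjusted p = 0.57) included mt-Nd6 at 194 ± 72.0 and 258 ± 14.7 and mt-Nd3 at 418 ± 131 and 290 ± 14.4. When wild-type replicate 3 was left out, the log2 fold change went from 0.48 to 0.24 for mt-Nd6, from -0.47 to -0.28 for mt-Nd3, from -0.56 to -0.28 for Tpi1, from -0.52 to -0.27 for Slc16a3 and from -0.48 to -0.31 for Ndufa6.

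Interferon response genes were the one list that was higher with the preset correlation. Its median was 0.16 relative to all genes (24 tested, 18 positive, camera adjusted p = 0.020, and 0.73 with an estimated correlation). It was 0.31 without wild-type replicate 3 (adjusted p = 4.1e-06, and 0.84 with an estimated correlation). No member passed over all genes, and 1 was higher adjusted over the list alone. Ifi44, an interferon-induced gene, had 0.0259 ± 0.0154 FPKM in wild-type and 1.06 and 2.77 in the knockout libraries. Rtp4 had 2.63 ± 0.394 and 4.77 ± 1.36, and Trim30a 5.03 ± 1.51 and 8.33 ± 1.26 (log2 fold change 0.66, and 0.43 without wild-type replicate 3). The list's call ended without wild-type replicate 1 (median 0.19, adjusted p = 0.13), wild-type replicate 2 (0.09, 0.69) or knockout replicate 1, where the median turned to -0.05 (adjusted p = 0.92). It also ended with a filter at 5 FPKM (median 0.06, adjusted p = 0.61) and with quantile normalization (0.10, 0.096), and the median was 0.29 without knockout replicate 2 and 0.31 with the replicate block.

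Activation and function lists otherwise did not pass with all libraries. Inflammatory cytokines and NF-kB targets (28 tested, 19 positive, camera adjusted p = 0.81) and alternative activation genes (15 tested, 11 positive, 0.81) had 0 members called over all genes and 0 adjusted over the list alone. The cytokine genes Il1a and Cxcl3 had 3.31 ± 1.48 and 8.74 ± 5.54 FPKM in wild-type against 7.15 ± 1.40 and 25 ± 11.8 in knockout, and the alternative activation genes Fn1 and Klf4 had 716 ± 139 and 3.92 ± 1.43 against 1068 ± 330 and 5.82 ± 0.553. Lysosomal genes (39 tested, 23 positive, adjusted p = 0.39) had 1 called member, Lyz2, which was also the 1 member called adjusted over the list alone. The lysosomal list passed without wild-type replicate 3, at a median of 0.10 (adjusted p = 0.00084), and not then with an estimated correlation (adjusted p = 0.84). The list holds Lyz1 and Lyz2, whose log2 fold changes were 1.15 and 5.89 without that library. It was not tested without these genes in any setting. With quantile normalization the lysosomal, chemokine receptor and NRF2 lists passed (adjusted p = 0.0011, 0.0034 and 0.043), and none of them did when the correlation was then estimated (adjusted p = 0.65, 0.75 and 0.75). Neuropilin ligands and co-receptors (15 tested, 12 positive, adjusted p = 0.57) held Sema4a at 40.2 ± 10.2 and 60.8 ± 0.579 and Vegfb at 31.9 ± 10.4 and 22.0 ± 1.51. Phagocytosis genes (24 tested, 12 positive, 0.67) held the Fc receptor gene Fcgr4 at 3.51 ± 0.715 and 5.92 ± 1.11 and the integrin gene Itgav at 38.5 ± 16.9 and 66.7 ± 0.710. Chemokine receptor and migration genes (32 tested, 25 positive, 0.12) held the formyl peptide receptor gene Fpr1 at 54.1 ± 10.5 and 80.6 ± 12.7. TGF-beta targets (18 tested, 8 positive, 0.57) held Thbs1 at 204 ± 99.8 and 419 ± 48.0 and Ctgf at 1.26 ± 0.279 and 0.585 ± 0.0608. Hypoxia genes (21 tested, 10 positive, 0.26) held P4ha2 at 10.1 ± 0.269 and 6.06 ± 2.42 and Egln3 at 9.54 ± 2.05 and 6.72 ± 0.90. NRF2 and antioxidant genes (23 tested, 14 positive, 0.80) held Slc7a11 at 26.3 ± 9.43 and 46.9 ± 8.33 and Gsr at 122 ± 87.6 and 207 ± 19.6. Gsr stood at 25 in wild-type replicate 3 against 196 and 145 in the other wild-type libraries, and without that library its log2 fold change went from 1.20 to 0.30. It went from 0.87 to 0.54 for Slc7a11, from 0.98 to 0.65 for Il1a, from 1.57 to 0.94 for Cxcl3, from 0.52 to 0.25 for Klf4, from 0.62 to 0.39 for Sema4a, from -0.47 to -0.23 for Vegfb and from 0.89 to 0.47 for Itgav.

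Mesothelial and fibroblast genes were lower as a list, at a median of -0.73 relative to all genes (6 of 18 members tested, all 6 negative, camera adjusted p = 9.8e-05, and 0.73 with an estimated correlation). The 6 were Bgn, Col1a1, Col1a2, Col3a1, Dcn and Sparc. The mesothelial markers Msln, Upk3b, Upk1b, Wt1, Lrrn4, Krt8, Krt18 and Krt19 fell under the filter, so the call says nothing about them. Without wild-type replicate 3 the median was -0.95 (adjusted p = 2.6e-10, and 0.84 with an estimated correlation), and without wild-type replicate 1 it was -0.48 (adjusted p = 0.012, and 0.68 with an estimated correlation). With no filter on low values the median was -0.19 for this list and -0.25 for mast cell genes. Col1a2, a collagen I chain, had 8.01 ± 2.10 FPKM in wild-type and 4.44 ± 1.20 in knockout, Bgn 6.77 ± 2.73 and 3.27 ± 0.624, and Sparc 14.9 ± 5.59 and 8.91 ± 0.407. No member was called, over all genes or adjusted over the list alone. MHC class II genes had a median of -0.57 (8 tested, 7 negative, adjusted p = 0.0032) and mast cell genes one of -0.47 (7 tested, all 7 negative, 0.022), and with an estimated correlation the adjusted p was 0.73 for both. The medians of both lists stood above the other libraries in wild-type replicate 3, by 1.18 and 1.48 on the log2 scale. There Cd74, the class II invariant chain, had 1270 FPKM against 318 to 611 in the other libraries, H2-Eb1 had 191 after realignment (0.0182 in its row as deposited) against 37.4 to 55.9, and Tpsb2, a mast cell tryptase, had 144 against 10.1 to 21.9. Without wild-type replicate 3 the medians were -0.07 and 0.23 (adjusted p = 0.29 and 0.60). The class II call also ended with no filter (median -0.13, adjusted p = 0.20), library weights (-0.18, 0.14), the replicate block (-0.07, 0.21) and the order as deposited (0.07, 0.56), and without wild-type replicate 2 the median was -1.11. The mast cell call also ended without knockout replicate 2 (median -0.14, adjusted p = 0.50). The median turned positive with library weights (0.12, 0.72) and the replicate block (0.23, 0.31), and stayed as large with median-of-ratios scaling (-0.47, 0.10) and quantile normalization (-0.51, 0.11), where the call ended as well. It was -0.80 without wild-type replicate 1 and -0.98 without knockout replicate 1. The mast cell genes Hdc and Cpa3 had 4.92 ± 3.28 and 3.50 ± 2.79 in wild-type and 1.70 ± 0.529 and 2.13 ± 0.576 in knockout. The log2 fold change of Tpsb2 without that library went from -0.74 to 0.42, that of Cpa3 from -0.37 to 0.11, that of Hdc from -0.96 to -0.56, that of Cd74 from -0.86 to -0.38, that of H2-Eb1 from -0.96 to -0.36 and that of Sparc from -0.61 to -0.94.

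Further marker lists did not pass with all libraries. Dendritic cell genes (6 tested, 3 positive, camera adjusted p = 0.091), which include Fscn1, passed without wild-type replicate 3 (median -0.33, adjusted p = 0.036, and 0.84 with an estimated correlation); Fscn1 was also called adjusted over the list alone, and Cd209a had 1.66 ± 0.451 and 1.05 ± 0.594 FPKM. Monocyte genes (6 tested, 3 positive, 0.57) held Cx3cr1, called adjusted over the list alone, and Ly6c2 at 13.8 ± 4.59 and 23.3 ± 4.11. Large peritoneal macrophage genes (26 tested, 12 positive and 14 negative, 0.57) held Naip1 at 3.72 ± 1.27 and 6.27 ± 0.268, besides Prg4 and, on the other side, Apoc1 (log2 fold change -1.06). B cell genes (5 tested, 3 positive, 0.57) held Cd22 at 6.37 ± 1.07 and 7.82 ± 0.798 and Blnk at 36.8 ± 4.93 and 31.4 ± 3.72, and neutrophil genes (5 tested, all 5 positive, 0.45) held Mmp8 at 19.6 ± 13.3 and 34.2 ± 8.43 and Mmp9 at 14.7 ± 6.53 and 20.6 ± 2.11. Lists with under 5 tested members were not tested as lists. The single tested T and NK cell gene, Il7r, had 11.0 ± 4.22 and 10.3 ± 2.65, the single eosinophil gene, Ear2, had 12.3 ± 4.04 and 7.66 ± 2.06, and 0 erythroid genes were tested. Leaving out wild-type replicate 3 took the log2 fold change from 0.56 to 0.15 for Mmp9, from 0.66 to 0.43 for Naip1, from -0.22 to -0.13 for Blnk, from -0.05 to -0.36 for Il7r and from -0.60 to -0.36 for Ear2. Of the 4 sex-linked genes tested 0 were called over all genes and 0 adjusted over the list alone, and of the 2 targeted loci Lyz2 was called over all genes, while adjusted over the list alone Lyz2 was higher and Nrp1 lower. The list median and the direction of the camera test differed for the sterol efflux, inflammatory cytokine and alternative activation lists, none of which passed.

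Ribosomal protein genes were lower in the knockout as a list, all 76 of them with a negative fold change and a median of -0.53 relative to all genes (camera adjusted p = 1.7e-22). With an estimated correlation the adjusted p was 0.73. Rpl21 had 276 ± 62.0 FPKM in wild-type and 175 ± 14.9 in knockout. No member passed, over all genes or adjusted over the list alone, and 14 had both knockout libraries under all wild-type libraries. Without wild-type replicate 3, where these genes stood above the other libraries by a median of 0.83, the median was -0.19 (adjusted p = 0.00011, and 0.84 with an estimated correlation), and without wild-type replicate 2 it was -0.81. It was -0.28 with quantile normalization, -0.32 with library weights and -0.19 with the replicate block. The libraries' deviations went with transcript length, at Spearman's rho of -0.32 in wild-type replicate 3 and 0.40 in knockout replicate 1. The other libraries had 0.06 to 0.18. No list was tested with trends of length and GC content removed. Replication histones, a list chosen as a possible sign of poly(A) selection, had a median of -0.49 (6 of 19 members tested, 5 negative, adjusted p = 0.0012, and 0.73 with an estimated correlation). Hist1h2bc had 20.9 ± 10.0 and 11.9 ± 1.15, and Hist2h2aa1 had 1.78 ± 0.124 and 1.14 ± 0.165. Whether poly(A) selection differed between the libraries was not tested. Unfolded protein and integrated stress response genes had a median of -0.25 (22 tested, 15 negative, adjusted p = 0.014, and 0.73 with an estimated correlation), with the chaperone gene Hspa5 at 191 ± 8.11 and 154 ± 21.1. Immediate early and heat shock genes had one of -0.23 (22 tested, 15 negative, adjusted p = 0.034, and 0.74 with an estimated correlation), with Hsp90aa1 at 134 ± 9.78 and 90.0 ± 23.2 and Ier3, on the other side, at 61.9 ± 13.8 and 85.9 ± 1.44. The histone call also ended without wild-type replicate 1 (median -0.39, adjusted p = 0.094), the unfolded protein call without wild-type replicate 1 (-0.18, 0.13), wild-type replicate 2 (-0.22, 0.090) or knockout replicate 2 (-0.12, 0.50), and the immediate early call without wild-type replicate 2 (-0.09, 0.72) or knockout replicate 2 (-0.05, 0.67). With quantile normalization and a filter at 5 FPKM both calls ended, for the unfolded protein list at medians of -0.17 for both (adjusted p = 0.12 and 0.067) and for the immediate early list at -0.18 and -0.20 (adjusted p = 0.14 and 0.067). The immediate early call also ended with library weights (-0.12, 0.078) and in the order as deposited (-0.24, 0.053), and its median was -0.37 without knockout replicate 1. With no filter the medians were -0.13 for the histones, -0.12 for the unfolded protein list and -0.14 for the immediate early list. Proliferation genes did not pass (15 tested, 8 positive, 0.45), with Cdk1 at 4.93 ± 1.89 and 2.60 ± 0.473 and Stmn1 at 2.30 ± 0.434 and 1.56 ± 0.316.

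**Figure D3:**
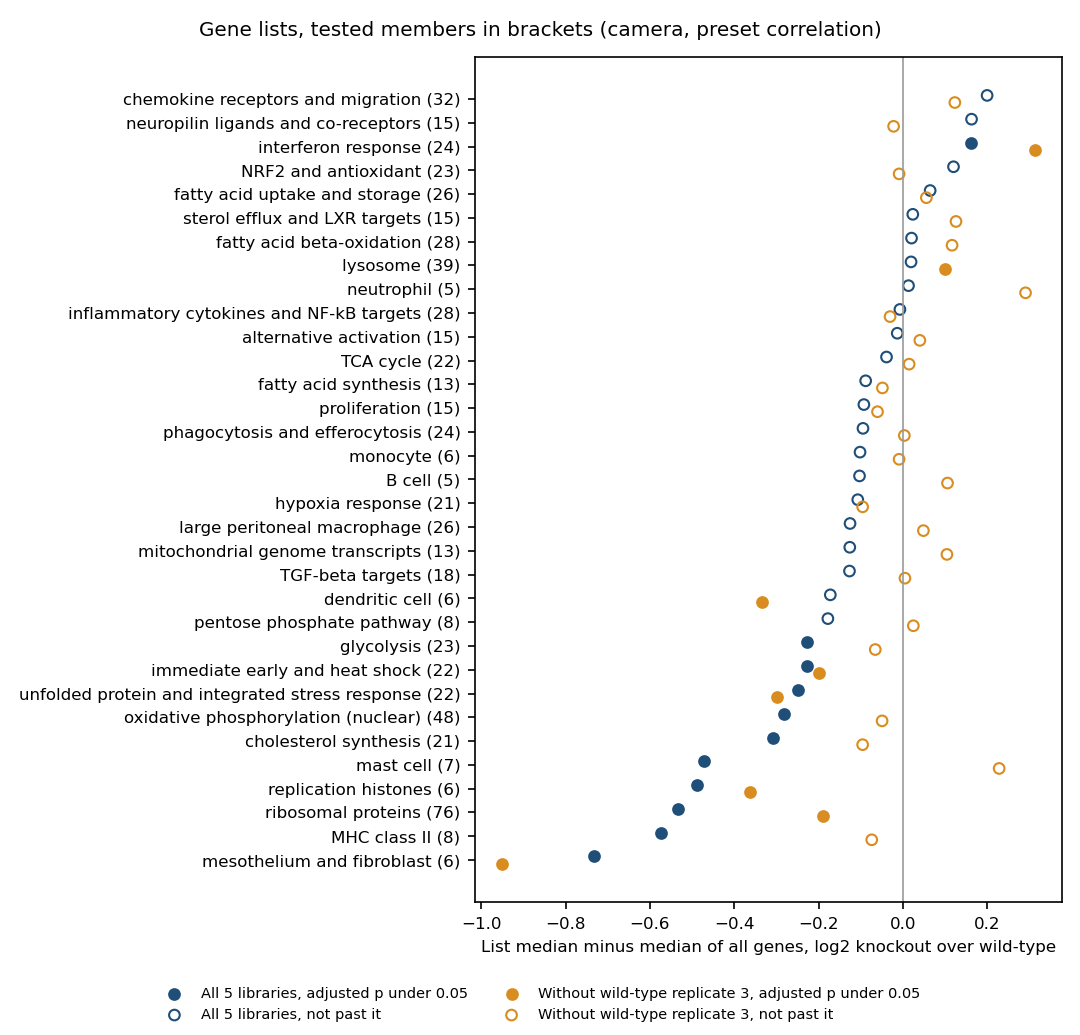
Each row is a gene list with its number of tested members; points give the list's median log2 fold change, knockout over wild-type, minus the median of all genes, with all 5 libraries (blue) and without wild-type replicate 3 (orange). Filled points passed camera with the preset correlation; with an estimated correlation 0 of 33 lists passed in all 5 libraries. The mesothelial and fibroblast list is lowest in both, at -0.73 and -0.95, and the mast cell list moves from -0.47 to 0.23.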

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

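The order of wild-type replicate 3 as deposited and the removal of genes with displaced rows were chosen after seeing the data, as were an estimated correlation together with quantile normalization or without wild-type replicate 1 or 3 and the rule that a sign change counts as a reversal only for a list or gene past the threshold in a setting; all other alternatives were planned, and those that need raw counts were not run. Nrp1 stayed negative under all 19 of them (-0.87 to -1.43) and passed with library weights alone (-1.43, limma adjusted p = 0.023; range over the alternatives 0.023 to 1.00). Lyz2 stayed past the threshold in each alternative that tested it. Its listed 0 in every wild-type library, with no spread, enters each of them, so they are not separate checks of that call. Without either knockout replicate Lyz2 fell under the filter. Genes higher in the knockout numbered 5, against 3 with a pseudocount of 0.1, 1 with no filter, 1 with a filter at 5 FPKM, 12 with library weights and 2 in the order as deposited; leaving out single libraries gave 0 to 7. Genes lower numbered 2, against 0 with no filter, 1 with a filter at 5 FPKM, 9 with library weights and 1 in the order as deposited; leaving out single libraries gave 0 to 7. The 0 higher after a knockout library is left out follows from the filter, and the lone library of that group is there assumed to vary like the wild-type ones; for the other differences the cause was not tested. Lists past the threshold numbered 11, against 4 at a filter of 5 FPKM, where 27 lists were testable, 7 with quantile normalization, 6 with library weights, 7 in the order as deposited, 0 with an estimated correlation and 0 with fry; leaving out single libraries gave 7 to 9. With an estimated correlation 0 passed under quantile normalization and 0 without wild-type replicate 1 or 3. The power of that setting was not tested, so the absence of calls does not show that the lists are unchanged. The interferon list's median, 0.16 with all libraries, ran from -0.048 to 0.31 on leaving out single libraries. The MHC class II median turned to 0.068 in the order as deposited, and the mast cell median to 0.12 with library weights; on leaving out single libraries the mast cell median ran from -0.98 to 0.23. List medians that were past the threshold in neither setting changed sign 27 times on leaving out single libraries and 38 times under other settings. The ribosomal and the mesothelial and fibroblast lists stayed past the threshold in each alternative that tested them except those with an estimated correlation and fry. With the order as deposited, the displaced genes left out and the realigned column, 2, 5 and 5 genes were higher, 1, 2 and 2 lower, and 7, 9 and 11 lists passed. With the displaced genes left out 31 lists were testable, and MHC class II was not among them. With the replicate number as a block 3 genes were higher and 1 lower, 7 lists passed and the mast cell median was 0.23. As wild-type replicate 3 is alone in its block, this is not a check apart from leaving that library out. Whether the numbers pair the libraries cannot be decided from 2 pairs (r of same-numbered deviations -0.05 and -0.01), where centring makes the crossed values their negatives, and no label says that they do. The 82 other named genes kept their side of the threshold under every alternative that tested them, with 15 changes of sign. The unknown depth leaves low genes without an interval, and simulated 2-fold changes were recovered in 13.2% of cases, so changes of that size can be missed.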

Other observations

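Among the most abundant protein-coding messages in both groups were those of iron storage, lipid transport and lysosomal digestion. Ferritin heavy chain Fth1 had 19243 to 25557 FPKM in the 4 libraries other than wild-type replicate 3, and Gm22133, a gene model with no assigned name, had 27176 ± 12883 in wild-type and 15642 ± 4113 in knockout. Ferritin light chain Ftl1 had 20928 ± 6994 FPKM in wild-type (SD, n = 3) and 15207 ± 2259 in knockout (SD, n = 2), apolipoprotein gene Apoe 16744 ± 2472 and 12615 ± 2018, serum amyloid gene Saa3 14193 ± 5174 and 11495 ± 2213, and cathepsin gene Ctsd 9099 ± 2094 and 7568 ± 110. The complement gene C1qb had 1435 and 1519 FPKM in wild-type replicates 1 and 2, 3672 in wild-type replicate 3, and 1373 and 1239 in the knockout libraries. Y-linked Ddx3y stood at 2.40 to 7.89 FPKM and Uty at 0.623 to 1.95 in all 5 libraries. Xist, the X-inactivation transcript, was at 1.33 in knockout replicate 2 and at or below 0.00132 in the other 4, a value chosen after it was seen.

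All tests below were chosen after the result was seen, except that of transcript length and GC content. Wild-type replicate 3 stood apart in 2 ways. In the displaced rows the row order accounted for the departure, with r across genes of 0.9162 after reordering. In the remaining rows its deviations went with transcript length (Spearman's rho -0.32 across genes, which are not independent) and GC content (rho 0.39), as did those of knockout replicate 1 with length (rho 0.40) and knockout replicate 2 with GC content (rho -0.39), and removing such trends from all libraries closed 21.2% ± 1.93 (bootstrap SD over genes) of its gap in r, too little for them to be the whole source. A lower share of macrophages, with the other cell types kept in proportion to each other, would raise all of them alike. The tested members of the lists did not show this. The mast cell genes stood at a median of 1.48 in that library on the log2 scale. The tested mesothelial and fibroblast genes stood at -0.477, with all 6 below 0, and were not corrected for length and GC trends. Mesothelial markers of that list fell under the filter and did not enter. They were mixed there, with Krt18 highest in that library (1.11 FPKM) and Wt1 not (0.274, against 0.472 in wild-type replicate 1). A lower share with other proportions, such as more mast and class II positive cells, stays open. A separate library batch and reads shared between genes stay open too, and the design names no biological difference within the wild-type group that could be tested.

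Lyz1 and Lyz2 had higher values in both libraries from mice that carry Cre in Lyz2, although Lyz1 did not pass the test. A mere shift of reads from one paralog to the other would keep their sum and could not raise both genes. The sum was 2361, 2071 and 832 FPKM in wild-type and 4733 and 5218 in knockout. It differed by 1.637 ± 0.612 (SE) on the log2 scale and by 1.17 without wild-type replicate 3. Lyz1 made up at least 98.8% of it in every library, so the sum mostly restates Lyz1. Both genes had higher listed values in both knockout libraries, which a mere shift between them could not give. For Lyz2 this rests on the listed 0 in wild-type, so it does not decide on a shift. The listed 0 for Lyz2 in wild-type may be a failed estimate. Fth1, above 1000 FPKM elsewhere, stood at 0 in wild-type replicate 3 after realignment and at 8.0 in its row as deposited. The cases are not alike, since Fth1 had 19243 to 25557 FPKM in the other libraries and Lyz2 at most 64.3. No value decides this. If the Lyz2 reads of wild-type cells were dropped, the sum is too low there and the listed values cannot speak on a shift. The insertion of Cre in the locus goes together with the genotype and cannot be told apart from loss of Nrp1 in these libraries.

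Nnt, at 4.94, 5.41 and 2.85 FPKM in wild-type and 10.1 and 9.01 in knockout, is a gene in which the C57BL/6J substrain carries a deletion, and the labels give the strain as C7/BL6 for wild-type and LysMCre-Nrp1fl/fl for knockout with no substrain, so a strain difference between the groups is a candidate explanation beside an effect of genotype. Its row is among the displaced ones, and in the order as deposited wild-type replicate 3 had 40.7 FPKM and the log2 fold change was -0.14. Without that library it was 0.7748 ± 0.14 (SE), 77.4% of the value with all libraries, and Nnt did not pass there either (limma adjusted p = 0.61). The rule that named Nnt takes only genes whose groups do not overlap. A positive value without that library was thus fixed in advance and cannot test the part of the low realigned value. Of 15 tested genes within 5 Mb of Nnt on chromosome 13, 0% had groups that do not overlap, against 20.9% elsewhere (Fisher's exact p = 0.052). This leaves a variant in Nnt alone open, as gene-level FPKM cannot show which exons the reads came from, and chance stays open too, since Nnt did not pass the adjusted threshold.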
